A study of Homo sapiens with 21 samples.

How the data were processed

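RNA from laser-captured lumbar spinal motor neurons of sporadic amyotrophic lateral sclerosis (sALS) and of controls was sequenced, each library carrying its own donor number in the labels. Per the labels' protocols, the neurons were dissected from frozen cord sections stained with cresyl violet, RNA of sufficient integrity was kept, and cDNA was amplified with a random-primed Ovation kit. The submitters' processing notes name the tools Bowtie, BWA, SAMtools and bedtools and the builds hg18, hg19, mm9 and mm10. Which tool and build served which step, and which annotation and read counter were used, is not given in the sources used here. No coordinates are therefore printed.

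The authors' deposited gene table holds the natural log of RPKM, reads scaled by transcript length and by the library's total, for each gene and library. The deposited values were found to include 1 read added to every gene. With that assumption, whole read numbers were recovered for 100% of the 25856 rows, within 0.002 reads or a relative 2e-08. The scale of each library followed its total of recovered reads over the rows, with a coefficient of variation of 0.143% across libraries. RPKM was scaled by these totals, so a few very abundant genes enter the scaling of every gene. A second deposited table of the authors gives each gene a score from 0 to 1, in columns headed Ratio MPR and Zscore MPR per the file headers. Its 14635 rows carry no values per library, its abbreviation is not explained in the sources used here, and it was only described.

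The labels list 21 samples, 8 controls and 13 sALS, whereas the series text counts 9 controls. Of the 21 columns of values per library, 20 matched a sample by name, 8 controls and 12 sALS. The other 1 column is a control column by its name, matched no sample and was not used, and 1 labelled sALS sample was not analysed here. Libraries are named by group and a replicate number. The comparison was therefore made on 12 sALS libraries in place of the planned 13. All 94 pairs of libraries within a group differed by more than sampling noise, the smallest chi-square per degree of freedom being 15.3 over genes with at least 20 reads in the pair. This does not exclude repeat amplifications of 1 sample, and libraries were counted once each because the labels give each its own donor number.

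Levels were computed as log2(RPKM + 1), with RPKM the exponential of the deposited value. X-inactivation and Y-linked genes, 107 rows, were left out of every step. Of all rows, 8344 had no read in any library, and 1525 of these shared a single deposited value in each library that passed the expression filter. Rows with no read were left out after results had been seen, and the filter as first written was kept as an alternative. Genes entered with an RPKM of at least 1 in at least 8 of the 20 libraries. For a symbol with several rows, the row with the highest mean was taken. This left 8672 genes. A gene low in controls could enter through sALS libraries where it was high, so counts and medians of lists of low genes can favour genes higher in sALS. The table's symbols were matched to current gene names by accession for 15349 rows, by symbol for 2434 and by alias for 1149, and 6924 rows were not matched and kept the name in the table.

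Groups were compared with limma 3.58.1 (lmFit and eBayes with a mean-dependent trend) in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over all genes tested and an adjusted p under 0.05. Log2 fold changes are sALS minus control and rest on means of log2(RPKM + 1). The averaging of log values and, for low genes, the added 1 can make them smaller than the ratio of mean RPKM. Lists of cell type markers, pathways and disease genes were tested with limma's camera at a preset correlation between genes of 0.01, and again with an estimated correlation, over the 43 lists with at least 5 tested genes. Camera compares a list with all other genes, so a list can be called lower while its own mean lies near 0. For each list the number of genes passing is given over all genes and adjusted over the list alone. Cell type scores are the mean of log2(RPKM + 1) over a list's tested genes. Differences in scores and in library measures were tested with a two-sided exact permutation test over all 125970 assignments of 8 of 20 libraries, the smallest possible p being 7.9e-06. These used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and the plots matplotlib 3.10.9.

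The groups, tests, lists, a first set of other settings and the rule for named genes were fixed before the data were examined. The rule named the 10 genes higher and the 10 lower with the largest log2 fold change among those passing, filled up by smallest p where fewer passed and without genes that carry only a sequence identifier. It also named up to 4 genes with the smallest p in each list, and TARDBP, SOD1, C9orf72, CHAT, STMN2, GFAP, MBP, CD68 and HLA-DRA, among others, whatever their result. Some genes that the rule names are not reported here. The settings fixed in this way changed the pseudocount, the filter, the scaling, the weighting of libraries, the covariates and the treatment of symbols with several rows, and left out each library in turn. Alternatives added after the data had been seen were the deposited log scale, limma voom on the recovered reads, leaving out the 3 libraries under 3000000 reads, thinning to the shallowest library, rescaling without the 10 highest genes, removing the added read, keeping rows with no read, joining the glial covariates with an estimated correlation and scoring all markers with a read. The correlation of the largest axis with the astrocyte score was also tested only after results had been seen.

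The recovered reads per library ran from 1938910 to 11182785 with a median of 6113254, and 1 read in a gene of median length corresponded to between 0.0216 and 0.124 RPKM. The reads come from amplified cDNA without molecular identifiers, so read numbers cover counting error only. The tests were run first on simulated data of 8672 genes in 20 libraries of the same group sizes, with 200 changed genes. Of these, limma recovered 82% at a log2 change of 1 and 99% at a log2 change of 2, and called 10 unchanged genes. Camera called 20 of 20 lists of 20 genes shifted by 0.5 log2 and 0 of 20 unchanged lists, but the simulated genes were independent of each other, which real genes are not. The labels give no batch, so none was modelled.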

Results

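Motor neurons, the large cholinergic cells of the ventral horn that drive skeletal muscle, degenerate in amyotrophic lateral sclerosis. The series compared RNA of motor neurons captured by laser from the lumbar cord of people with the sporadic form (sALS) and of controls. Gene expression was available here for 8 control and 12 sALS libraries. The control libraries held 3448657, 8423940, 6388580, 9006376, 6376908, 7969555, 4535279 and 3159692 recovered reads, in the order control 1 to control 8. The sALS libraries held 7413345, 6141057, 6583497, 2782669, 2889962, 11182785, 3431983, 10354158, 4752311, 6085451, 5050810 and 1938910 reads, in the order sALS 1 to sALS 12. Depth was 6163623 ± 2254960 reads in controls (SD, n = 8) and 5717245 ± 2904451 reads in sALS (SD, n = 12), a difference that did not pass an exact permutation test (p = 0.716, adjusted p = 0.716 over 5 library measures). A read was found for 13136 ± 595 genes per control library and 13444 ± 793 genes per sALS library (exact permutation p = 0.361, adjusted p = 0.452).

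Neurofilament transcripts were abundant in the captured material of both groups. These genes, which encode the intermediate filaments of large axons, took 26.5 ± 3.89% of reads in controls (SD, n = 8) and 20.9 ± 6.51% in sALS (SD, n = 12). The difference of -5.58 percentage points had an exact permutation p = 0.0449 and did not pass after adjustment over the 5 library measures (adjusted p = 0.0889), with 10 of 12 sALS libraries below the control median. NEFM, the medium neurofilament chain, stood at 31146 ± 3735 RPKM in controls and 23313 ± 8294 RPKM in sALS (log2 fold change -0.50, limma adjusted p = 0.217). CHAT, the enzyme that makes acetylcholine, was at 2.36 ± 2.34 RPKM in controls and 2.33 ± 2.13 RPKM in sALS (log2 fold change -0.025, 0.21 without control 1, adjusted p = 0.972). The largest axis of variation among libraries carried 40.7% of the variance, and sALS libraries lay higher on it (exact permutation p = 0.00867, adjusted p = 0.0433, 10 of 12 above the control median). Position on this axis went with the astrocyte score across the 20 libraries (Pearson's r 0.969, Spearman's rho 0.958, p = 1.0e-05 from 100000 permutations, the smallest possible, r 0.968 without the 2 libraries farthest out on the axis), and within controls (r 0.943) and sALS (r 0.978). The markers are among the genes behind the axis, and its sign was set so that it rises with the astrocyte score. sALS 5 stood apart most, with a median correlation of 0.763 with the other libraries.

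Markers of glial, immune and vascular cells were higher in the sALS captures, while marker scores of neurons did not pass a test. The microglia and macrophage score rose by 1.29 ± 0.32 log2 units (SE, exact permutation p = 0.00364, adjusted p = 0.0160), with 12 of 12 sALS libraries above the control median. The astrocyte score rose by 1.22 ± 0.40 (p = 0.0104, adjusted p = 0.0234, 11 of 12) and the oligodendrocyte score by 1.11 ± 0.37 (p = 0.0183, adjusted p = 0.0329, 9 of 12), both by the exact permutation test. The Schwann cell score rose by 1.25 ± 0.35 (adjusted p = 0.0160, 11 of 12) and the endothelial score by 1.06 ± 0.24 (adjusted p = 0.0160, 10 of 12) in the same test. Of the 6 genes in the Schwann cell score 2 also stand in another glial list, so it is not fully separate from the glial scores. The astrocyte call was lost without control 2 (1.09, adjusted p = 0.0528). The oligodendrocyte call was lost without control 2 (1.04, adjusted p = 0.0598), control 3 (1.02, 0.0641), control 8 (0.996, 0.0691), sALS 1 (1.03, 0.0525), sALS 2 (1.01, 0.0532), sALS 5 (0.97, 0.0529), sALS 10 (1.06, 0.0505) or sALS 11 (1.01, 0.0532). By the exact permutation test the motor neuron score differed by -0.12 ± 0.16 (adjusted p = 0.589, 7 of 12 below the control median), the pan-neuronal score by -0.03 ± 0.12 (adjusted p = 0.856, 6 of 12 below) and the interneuron score by 0.44 ± 0.31 (adjusted p = 0.259, 10 of 12 above). The score of neurofilaments and large neurons differed by -0.26 ± 0.13 (adjusted p = 0.121, 9 of 12 below), and this passed when each library was centred on its median (-0.48, adjusted p = 0.0223) or rescaled without the 10 highest genes (-0.37, adjusted p = 0.0405). Under the same settings the motor neuron score was at -0.34 (adjusted p = 0.182) and -0.22 (0.323), and the pan-neuronal score at -0.25 (0.182) and -0.14 (0.408). Of 15 endothelial markers only 5 passed the expression filter, and of these only 1 had a control mean of at least 1 RPKM. So did 4 of 12 microglia markers, and the filter could thus favour markers high in sALS. Over all markers with a read the differences were smaller and still passed: 0.87 for microglia (adjusted p = 0.0165), 1.16 for astrocytes (0.0227), 0.97 for oligodendrocytes (0.0342), 0.57 for endothelium (0.0165) and 0.89 for Schwann cells (0.0165). With a pseudocount of 0.1 the microglia score differed by 2.02 (adjusted p = 0.0119) and the endothelial score by 1.76 (0.0119).

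**Figure D1:**
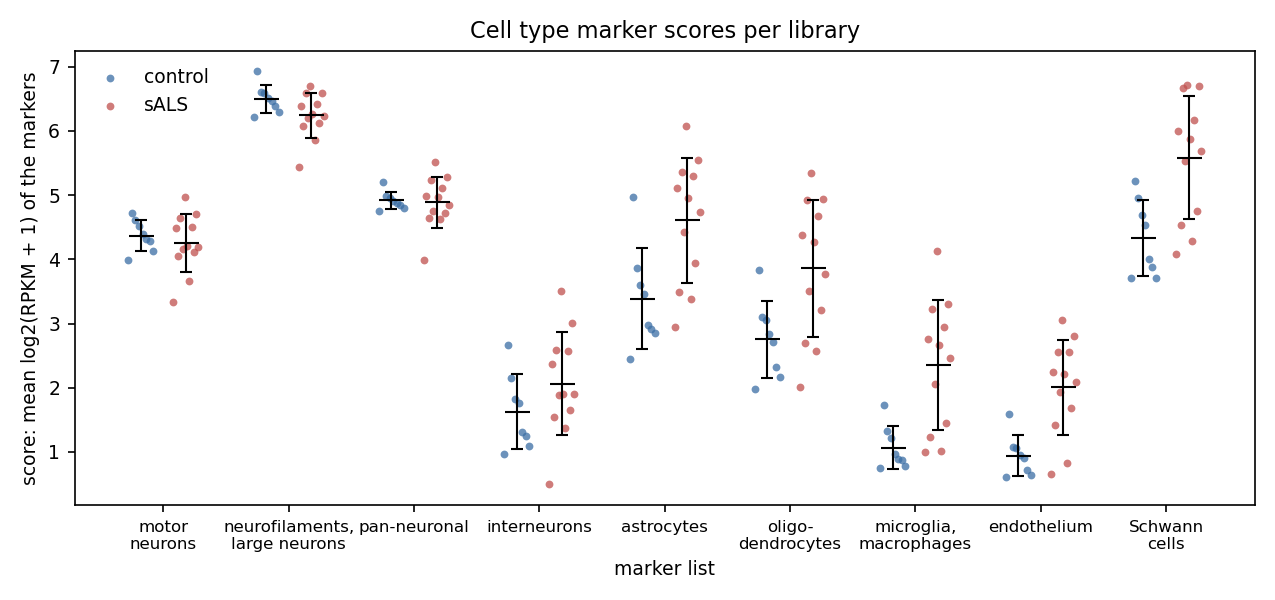
Marker score of 9 cell type lists (mean log2(RPKM + 1) of the markers, y axis) in the 8 control and 12 sALS libraries, with 1 point per library and bars at mean ± SD. The scores of astrocytes, oligodendrocytes, microglia, endothelium and Schwann cells are higher on average in sALS by 1.06 to 1.29 log2 units, with 5, 6, 8, 9 and 8 of 12 sALS libraries above the highest control in this order. All 9 scores overlap between the groups.

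Among 12 microglia and macrophage genes, 2 rose over all genes tested and 11 adjusted over the list alone. They included ITGB2, the shared beta chain of leukocyte integrins, from 2.05 ± 1.24 RPKM (SD, n = 8) to 14.8 ± 11.3 RPKM (SD, n = 12), and GPNMB, a glycoprotein of phagocytes, from 22.6 ± 7.40 to 61.9 ± 39.1 RPKM. AIF1, a calcium-binding protein of microglia, had a log2 fold change of 1.27 without passing (limma adjusted p = 0.0603), and the lysosomal protein CD68 one of 1.51 (adjusted p = 0.0634). Among 16 astrocyte genes 1 rose, ID3, an inhibitor of helix-loop-helix transcription factors (1.19, adjusted p = 0.0474, 11 of 12), and 11 rose adjusted over the list alone. ID3 reached at most 0.62 RPKM in controls, so it passed the expression filter through sALS libraries alone. GFAP, the filament of astrocytes, was at 6.04 ± 5.73 RPKM in controls and 25.8 ± 23.0 RPKM in sALS (log2 fold change 1.77, adjusted p = 0.0799). Among 15 oligodendrocyte genes 2 rose, the small heat shock protein CRYAB (1.76, adjusted p = 0.0418, 12 of 12) and the myelin proteolipid MAL (1.46, adjusted p = 0.0474, 12 of 12), and 12 rose adjusted over the list alone. MBP, myelin basic protein, was at 62.3 ± 41.0 RPKM in controls and 223 ± 169 RPKM in sALS (1.63, adjusted p = 0.0896). PECAM1, an adhesion molecule of endothelium, rose (1.42, adjusted p = 0.0418, 11 of 12), the 1 of 5 endothelial genes to do so, with 5 of 5 adjusted over the list alone. None of 6 Schwann cell genes rose over all genes by limma, whereas 6 rose adjusted over the list alone, 2 of which also stand in another glial list; the peripheral myelin protein PMP2 had a log2 fold change of 2.23 (adjusted p = 0.0602). Camera called all 5 lists higher at its preset correlation, and none with an estimated one (adjusted p = 0.202 with an estimated correlation for microglia, endothelium and Schwann cells, 0.230 for astrocytes and 0.305 for oligodendrocytes).

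Over all genes, more rose than fell in sALS. Of 8672 genes, limma called 70 higher and 10 lower at an adjusted p under 0.05, and 1599 and 294 had an unadjusted p under 0.05. Among the named genes the largest rise in the main fit was that of APOD, a lipid carrier of glia, from 25.1 ± 22.4 RPKM (SD, n = 8) to 192 ± 182 RPKM (SD, n = 12), a log2 fold change of 2.71 ± 0.61 (SE, adjusted p = 0.0409, 10 of 12 libraries above the control median). IGF2, an insulin-like growth factor, rose from 3.25 ± 3.19 to 34.6 ± 33.6 RPKM (2.63 ± 0.56, adjusted p = 0.0382, 11 of 12). CD9, a tetraspanin of the cell surface, rose from 1.497 ± 1.28 to 13.9 ± 10.7 RPKM (2.27 ± 0.43, adjusted p = 0.0363, 12 of 12). Also higher were tissue factor F3 (2.36), the mRNA decay factor ZFP36L1 (2.29), the water channel AQP1 (2.16), cyclin D1 (CCND1, 2.14), the chemokine receptor CXCR4 (2.12), the invariant chain CD74 (2.10) and ITGB2 (2.01). For these 7 the adjusted p ran from 0.0366 to 0.0436, and at least 11 of 12 sALS libraries lay above the control median. At least 2-fold changes made up 50 of the 70 genes higher and 3 of the 10 lower. These counts depend on the pseudocount, with 60 and 6 of the same genes at a pseudocount of 0.1 and likewise on the deposited log scale. The order by size also depends on the setting. Over the alternatives that kept every library or left out the 3 shallow ones, APOD reached at most 2.82, against 3.68 for CXCR4, 3.39 for F3 and 3.17 for IGF2.

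PRUNE2, a BCH-domain protein abundant in nervous tissue, fell from 309 ± 46.3 RPKM (SD, n = 8) to 124 ± 58.9 RPKM (SD, n = 12), a log2 fold change of -1.49 ± 0.28 (SE, limma adjusted p = 0.0363). KCNA1, a delayed rectifier potassium channel of axons, fell from 61.6 ± 6.47 to 37.9 ± 10.0 RPKM (-0.72 ± 0.15, adjusted p = 0.0366). ELAVL3, a neuronal RNA-binding protein, fell from 4.34 ± 1.73 to 2.07 ± 0.77 RPKM (-0.78 ± 0.19, adjusted p = 0.0454). CUX2, a homeobox transcription factor, fell from 2.43 ± 1.34 to 0.73 ± 0.44 RPKM (-0.96 ± 0.19, adjusted p = 0.0363). C11orf87 (-1.12), FAM83D (-0.87), the chloride transporter CLCN5 (-0.85) and the actin-binding coronin CORO2A (-0.67) also fell, with adjusted p from 0.0409 to 0.0490. A further 2 genes that fell carry only sequence identifiers. The kinase MAP2K4 (-0.82) and the ubiquitin ligase MYCBP2 (-0.51) came next and did not pass, both with an adjusted p of 0.0506. Of the 10 genes named in this direction, CLCN5 and MYCBP2 were lower than the control median in 11 of 12 sALS libraries and the others in 12 of 12.

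**Figure D2:**
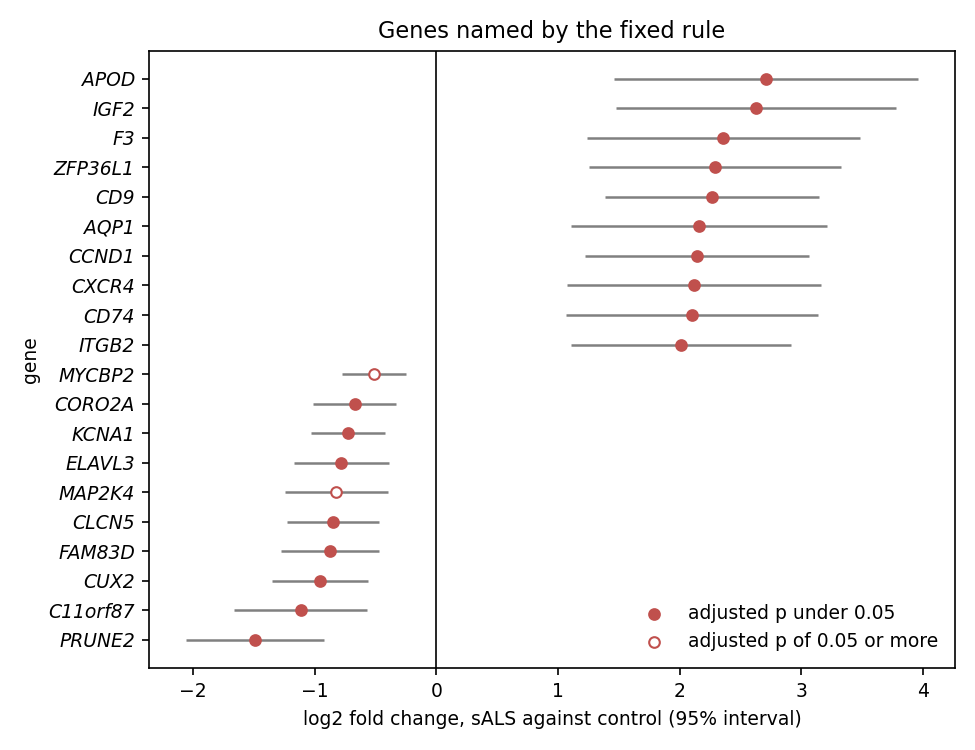
Log2 fold change, sALS against control, of the 10 genes higher and 10 lower named by the fixed rule (x axis), with 95% intervals from limma. Filled points passed an adjusted p of 0.05, and the open points MAP2K4 and MYCBP2 did not.

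These gene counts depended on single libraries and on the model. Without control 2, control 3, control 4, control 5, control 6, control 8, sALS 1 or sALS 9, limma called 0 genes higher and 0 lower, with between 1572 and 1992 genes at an unadjusted p under 0.05. No gene named here as rising or falling was therefore called when any of those 8 libraries was left out. It called 1 and 0 without control 1, 1 and 0 without sALS 11, 2 and 0 without sALS 10, 2 and 1 without sALS 2, 2 and 2 without sALS 7, 4 and 2 without sALS 12 and 24 and 3 without sALS 5. It called 184 and 19 without sALS 3, 429 and 28 without control 7, 527 and 42 without sALS 4, 560 and 57 without sALS 8 and 611 and 53 without sALS 6. With the astrocyte, oligodendrocyte and microglia scores as covariates limma called 0 and 0 genes (280 at an unadjusted p under 0.05), and voom on the recovered reads 0 and 0 (1635 at an unadjusted p under 0.05). The median log2 fold change of all 8672 genes was 0.14, against -0.09 when libraries were centred on their medians. The split was 70 higher and 10 lower as deposited, 64 and 40 with median centring, 64 and 34 with quantile normalization and 95 and 26 when rescaled without the 10 highest genes. All 80 genes called, PRUNE2, KCNA1, APOD, IGF2 and CD9 among them, kept their sign under each alternative in which they were tested. These genes were chosen by p in the same libraries, so a kept sign was likely in advance. Their size did not hold with the 3 glial scores as covariates, where the log2 fold change was 0.75 for APOD, 1.18 for IGF2, 0.99 for CD9, 0.22 for CD74, 0.21 for FTL, -0.31 for KCNA1 and -0.85 for PRUNE2. The glial scores themselves differ between the groups, so this loss of size does not give its cause.

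**Figure D3:**
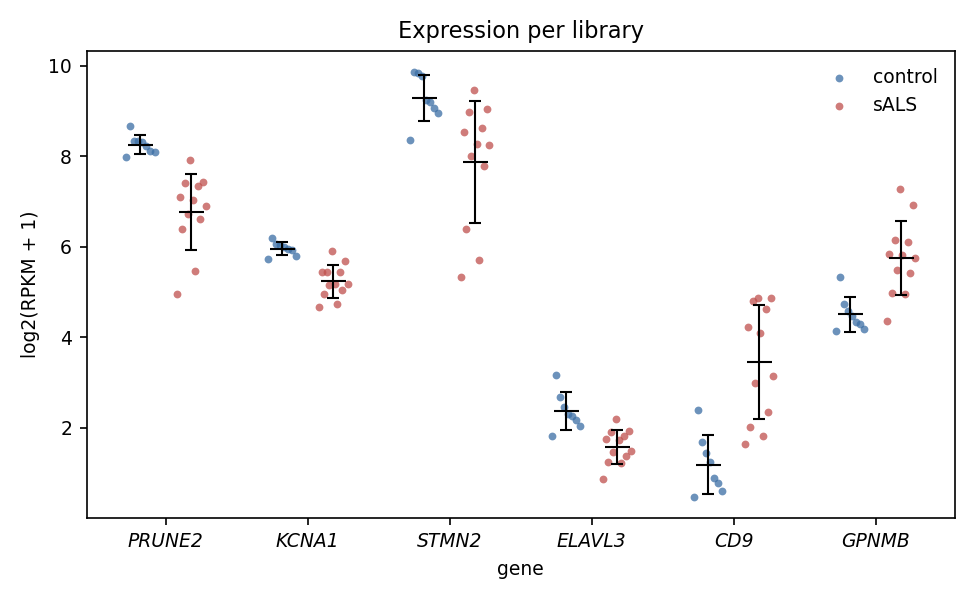
Expression, log2(RPKM + 1) on the y axis, of 6 genes in the 8 control and 12 sALS libraries, with 1 point per library and bars at mean ± SD. PRUNE2, KCNA1 and ELAVL3 fell by 1.49, 0.72 and 0.78 log2 units, CD9 and GPNMB rose by 2.27 and 1.24, and STMN2 (-1.42) did not pass.

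Among 43 lists tested, camera called 18 higher and 11 lower at its preset correlation of 0.01. With an estimated correlation camera called 0 of the 43, the smallest adjusted p being 0.202 and the smallest unadjusted p 0.0144. Each of the 18 lists called higher also passed the exact permutation test of its own score, and 0 of the 11 called lower did (smallest unadjusted p = 0.0804, adjusted p = 0.122). In 99 random splits of the libraries camera at its preset correlation called at least 1 list in 91, at least 10 in 40 and a median of 7, so its calls went beyond their nominal error rate. The 11 lists were thus lower relative to other genes, with means and medians below 0. Given the 3 glial scores as covariates, camera called 5 lists higher and 1 lower, leaving out the 3 glial lists, whose change is then fixed at 0. With these covariates and an estimated correlation together it called 0 and 0.

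Lists of extracellular matrix and immune genes were called higher by camera at its preset correlation. Of 21 extracellular matrix genes 3 rose over all genes and 17 adjusted over the list alone, with a median log2 fold change of 1.06 (adjusted p = 0.204 with an estimated correlation). They were fibronectin (FN1, 1.77), the laminin chain LAMA2 (1.33) and fibulin-5, listed as FIBL-5 (1.47), while biglycan (BGN, 1.63) did not pass (limma adjusted p = 0.0529). Of 11 genes of MHC class I and II 4 rose and 9 adjusted over the list alone (median 1.23, adjusted p = 0.204 with an estimated correlation), the class II chains HLA-DPA1 (1.89) and HLA-DPB1 (1.76), the class I chain HLA-C (1.23) and CD74 (2.10). HLA genes have near-identical copies, so reads may be split between them and their values are uncertain. Of 12 complement genes 2 rose and 9 adjusted over the list alone (median 0.95, adjusted p = 0.202 with an estimated correlation), the inhibitor SERPING1 (1.80) among them, while the components C3 (1.29, adjusted p = 0.0629) and C7 (1.52, adjusted p = 0.0554) did not pass. Of 15 interferon response genes 1 rose, the guanylate-binding GTPase GBP2 (1.35), and 9 rose adjusted over the list alone (median 0.76, adjusted p = 0.204 with an estimated correlation). Of 8 genes of cytokines, chemokines and NF-kB targets none rose over all genes by limma and 6 adjusted over the list alone (median 0.97, adjusted p = 0.204 with an estimated correlation). The chemokine CXCL12 had a log2 fold change of 2.04 (limma adjusted p = 0.0598). Of the listed genes with a read, the expression filter kept 8 of 27 for cytokines, 21 of 40 for matrix, 11 of 17 for MHC, 12 of 22 for complement and 15 of 23 for interferon response. The filter could favour genes high in sALS here too. GBP2 reached at most 0.80 RPKM in controls, so it entered through sALS libraries alone. The astrocyte score rose by 1.22 and the microglia score by 1.29 in the same libraries. With these and the oligodendrocyte score as covariates, the mean log2 fold change went from 1.03 to 0.06 for matrix, 1.18 to 0.16 for MHC, 0.93 to 0.10 for complement, 0.78 to 0.07 for interferon response and 1.01 to 0.08 for cytokines. Because the covariates themselves differ between the groups, this fall cannot tell cell content from a response of glial or immune cells.

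Genes of reactive glial states were higher as well, in lists that share members with the astrocyte and microglia lists. Of 15 reactive astrocyte genes none rose over all genes by limma and 11 adjusted over the list alone (median 1.36, adjusted p = 0.202 with an estimated correlation). CD44, a hyaluronan receptor (2.05, adjusted p = 0.0529), and the filament protein vimentin (VIM, 2.03, adjusted p = 0.0532) did not pass. CD44 and VIM also stand in the astrocyte list, whose score rose by 1.22, so the rise of the reactive list is not separate from it. With the glial scores as covariates the mean of the reactive list went from 1.27 to 0.03, a fall that shared genes partly build in. Of 9 disease-associated microglia genes 3 rose and 7 adjusted over the list alone (median 1.24, adjusted p = 0.202 with an estimated correlation), CD9 (2.27), GPNMB (1.24) and the ferritin light chain FTL (1.39). GPNMB also stands in the microglia list, whose score rose by 1.29. The mean of the disease-associated list went from 1.05 to 0.29 with the covariates, and camera still called this list at the preset correlation (adjusted p = 0.0272, and 0.514 with an estimated one).

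The lists of ribosomal protein and splicing genes were called higher at camera's preset correlation too. Of 42 cytosolic ribosomal protein genes 6 rose over all genes and 36 adjusted over the list alone, with a median log2 fold change of 0.69 (adjusted p = 0.202 with an estimated correlation). RPL30 rose from 10.2 ± 2.51 RPKM (SD, n = 8) to 19.8 ± 6.57 RPKM (SD, n = 12, log2 fold change 0.87, limma adjusted p = 0.0409, 10 of 12), and RPL37A (0.94), RPL19 (0.83) and RPL38 (0.83) rose in 11 of 12. Ribosomal protein genes have many processed pseudogenes, so their read numbers are uncertain. Of 41 RNA-binding and splicing genes 2 rose and 18 adjusted over the list alone (median 0.33, adjusted p = 0.342 with an estimated correlation), the serine- and arginine-rich splicing factors SFRS1 (0.79, adjusted p = 0.0366, 12 of 12) and SFRS7 (0.74, adjusted p = 0.0474, 12 of 12). HNRNPH3 (0.79, adjusted p = 0.0537) and HNRNPA2B1 (0.60, adjusted p = 0.0634), both heterogeneous ribonucleoproteins, did not pass. The size depended on the scaling: the mean of RNA-binding genes went from 0.41 to 0.18 with median centring and 0.25 with quantile normalization. That of ribosomal proteins went from 0.67 to 0.45 and 0.49. When the 3 glial scores, which rose by 1.11 to 1.29, were covariates, the mean went from 0.67 to 0.18 for ribosomal proteins, still called at the preset correlation (adjusted p = 4.2e-05, and 0.796 with an estimated one), and from 0.41 to 0.04 for RNA-binding genes.

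Genes linked to ALS by inheritance were not called as a group. Of 29 tested, none passed over all genes by limma (median 0.14, beside 0.14 for all genes, camera adjusted p = 0.971), and 4 rose adjusted over the list alone. TARDBP, which encodes TDP-43, was at 45.0 ± 10.2 RPKM in controls (SD, n = 8) and 58.8 ± 11.2 RPKM in sALS (SD, n = 12, log2 fold change 0.39, adjusted p = 0.136, 11 of 12 above the control median). Superoxide dismutase SOD1 had a log2 fold change of -0.12 (adjusted p = 0.776) and C9orf72 one of -0.034 (adjusted p = 0.945), which turned to 0.044 without sALS 10. The autophagy receptor SQSTM1 (0.57, adjusted p = 0.0629) did not pass. Of 15 transcripts that depend on TDP-43, 1 fell over all genes, ELAVL3 (-0.78), and 3 fell adjusted over the list alone (mean -0.15, median -0.18, adjusted p = 0.202 with an estimated correlation). STMN2, a microtubule regulator of growing axons whose RNA is misspliced when TDP-43 is lost, was at 660 ± 222 RPKM in controls and 314 ± 205 RPKM in sALS (-1.42 ± 0.44, adjusted p = 0.0742, 11 of 12 below the control median). PSD3 (-0.57, adjusted p = 0.0760) and POLDIP3 (0.50, adjusted p = 0.183) did not pass. STMN2 and ELAVL3 also stand in the neuronal marker lists. Over the 13 list genes outside those lists, the score difference exceeded that of the neuronal genes (-0.08) by 0.08 (exact permutation p = 0.685). The list mean thus rests largely on STMN2 and ELAVL3. The mean of the TDP-43-dependent list was -0.38 with median centring, -0.34 with quantile normalization, -0.24 when rescaled without the 10 highest genes and -0.28 with the 3 glial scores as covariates (camera adjusted p = 3.2e-04, and 0.514 with these covariates and an estimated correlation).

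Of the 4 neuronal lists 3 were called lower relative to other genes, and interneuron markers were not called (median 0.44, 5 of 5 genes above 0, camera adjusted p = 0.600). Neurofilament and large neuron genes had 1 of 15 lower over all genes, KCNA1, and 3 adjusted over the list alone (median -0.24, adjusted p = 0.202 with an estimated correlation). The tubulin TUBB3 (-0.72, limma adjusted p = 0.102) did not pass. Motor neuron genes had 0 of 12 passing by limma (median -0.03, adjusted p = 0.221 with an estimated correlation); CHODL, a lectin of fast motor neurons, had a log2 fold change of -0.92 (adjusted p = 0.151). Pan-neuronal genes had 1 of 18 lower, ELAVL3, and 1 adjusted over the list alone (median -0.07, adjusted p = 0.385 with an estimated correlation). Camera's calls for motor neuron and pan-neuronal genes were lost without sALS 5 (means -0.03, adjusted p = 0.0558, and 0.05, adjusted p = 0.103). The motor neuron call was also lost with median centring (-0.34, adjusted p = 0.0715), quantile normalization (-0.27, 0.0901) and a mean RPKM of at least 5 (-0.12, 0.114). The pan-neuronal call was also lost with quantile normalization (-0.17, 0.0668), array weights (0.04, 0.0623), a mean RPKM of at least 5 (0.01, 0.122) and without the 3 libraries under 3000000 reads (0.08, 0.0921). Of 30 voltage-gated ion channels 1 fell, KCNA1, and 1 adjusted over the list alone (median -0.14, adjusted p = 0.202 with an estimated correlation), and the sodium channel SCN1A (-0.63, adjusted p = 0.120) did not pass. With the 3 glial scores, which rose by 1.11 to 1.29, as covariates the mean went from -0.26 to -0.02 for large neurons, -0.12 to 0.14 for motor neurons, -0.03 to 0.16 for pan-neuronal genes and -0.08 to -0.02 for ion channels.

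In the authors' deposited table of MPR values, the Ratio MPR of a gene followed the log2 fold change across the 8668 tested genes found in it (Spearman's rho 0.935), and the Zscore MPR likewise (rho 0.927). These correlations are across genes, which are not independent replicates. The MPR values belong to the same series, so they give no independent support. The median Ratio MPR in the authors' deposited table was 0.900 for the 70 genes higher, APOD and IGF2 among them, 0.0964 for the 10 lower and 0.476 for all tested genes. The 70 and 10 genes were chosen by p in the libraries of this series.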

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

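The tests of cell content, depth and a few abundant genes for the glial markers, of depth and the glial covariates for the TDP-43-dependent list and of the glial covariates for the ribosomal list were chosen only after those results had been seen. In the 8 control libraries, 8 of 94 scores and genes had a library farther from the others than Dixon's 95% critical value allows, and chance gives about 5% of such groups. Control 7 was the library concerned in 4 of them. Its endothelial score was 1.59 against 0.61 to 1.07 in the others (gap over range 0.529), and its PECAM1 level was 1.69 RPKM against 0.107 to 0.605 (0.581). Its CD44 level was 28.5 RPKM against 3.74 to 9.06 (0.588), and its AIF1 level 3.58 RPKM against 0.0620 to 0.573 (0.731). CUX2 was at 5.57 RPKM in control 5 against 1.55 to 2.87 in the others (0.560). CHAT was at 8.003 RPKM in control 1 against 0.778 to 2.35 (0.609), and CD68 at 1.65 RPKM in control 4 against 0.0702 to 0.607 (0.552). HNRNPA2B1 was lowest in control 6, at 54.2 RPKM against 87.5 to 125 RPKM (0.571).

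The first pattern weighed was the rise of glial, immune and vascular markers in sALS libraries. Thinning all libraries to equal depth kept at least 99.6% of each of the 3 differences, and rescaling without the 10 highest genes kept at least 89.9%, which argues against depth or a few abundant genes. More RNA of other cell types in the captures and a response of glia cannot be told apart: over all markers with a read, on the deposited scale in log2 units, the microglia score rose by 1.99 against 1.48 for astrocytes and 1.31 for oligodendrocytes, a contrast of 0.60 ± 0.26 (SE, exact permutation p = 0.0484), which did not pass over markers under 10 RPKM in controls (0.51, p = 0.0750). The contrast was 0.89 (exact permutation p = 0.00456) over the markers kept by the expression filter. That filter lets a low marker in where sALS libraries raise it, so this value decides nothing. The neurofilament share of reads was lower in sALS, as more RNA of other cells would give, at an exact permutation p = 0.0449. It did not pass after adjustment over 5 library measures (adjusted p = 0.0889). More microglia around diseased neurons, or a change of state in them, may contribute, and this was not tested.

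The second pattern was camera's call of TDP-43-dependent transcripts as lower relative to other genes, which was lost at an estimated correlation (adjusted p = 0.202), while the list's own score did not pass (-0.15, exact permutation p = 0.158). The glial covariates cannot decide on dilution of neuronal RNA. With them the group coefficient of the list score was -0.28 (95% interval -0.53 to -0.03) against -0.15 (-0.37 to 0.06) without them. That of the neuronal score went from -0.08 to 0.14 (-0.18 to 0.45). But STMN2 and ELAVL3, which also stand in neuronal lists, were kept in the list score and left out of the neuronal score. The glial scores also differ between the groups, and the covariates were not run on the 13 list genes outside the neuronal lists. Without covariates the list score minus the neuronal score did not pass (0.08 without shared genes, exact permutation p = 0.685, and -0.07 with all 15 list genes, p = 0.652). Camera with the covariates and an estimated correlation did not call the list (adjusted p = 0.514), so dilution stays open. Thinning to equal depth kept 117% of the mean change (adjusted p = 6.8e-04), which argues against depth. Loss of TDP-43 function in sALS neurons may contribute but was not tested, since gene-level values do not show splicing.

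The third pattern was the rise of ribosomal protein genes. Random lists matched on implied length argue against transcript length as the cause: their medians lay around 0.14, against 0.69 for the ribosomal genes. Of 10000 such lists 0% had a median as high, with 0.25 at the upper end of the central 95%. That spread is too narrow to judge the 0% by, since the lists drew genes independently whereas ribosomal genes vary together (estimated correlation 0.518). The lists were not matched on expression level. With the 3 glial scores as covariates the group coefficient was 0.18 (95% interval -0.03 to 0.40) against 0.67 (0.32 to 1.02) without them, so RNA of other cells and a rise within neurons cannot be told apart, because the interval includes 0 while the glial scores themselves differ between the groups. A change in translation genes of sALS motor neurons stays open and was not tested.

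The count of genes was seldom reached by random splits, but chance is not excluded. Of 100 splits of the 20 libraries into groups of 8 and 12, 2 called as many genes, the real one included, with 80 genes in the real split and 1430 in the highest other. That other split called many times the real number, so a random split can call more genes than the real one. What separates its libraries, and how far it overlaps the real groups, was not tested. The count of lists was as high in 3 of 100 splits, the real one included, with 29 lists in the real split and 30 in the highest other. Chance is not excluded there either. Of the 99 random splits 91 called at least 1 list, 40 at least 10 and the median was 7, so a single list called at the preset correlation is weak evidence.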

How the results depend on the processing

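The deposited log scale, voom, thinning, rescaling, scores of unfiltered markers, the glial covariates joined with an estimated correlation, leaving out the 3 libraries under 3000000 reads, removing the added read and keeping rows with no read were chosen after seeing the data; the other alternatives were planned. All 5 glial, immune and vascular scores passed under the 8 alternatives run on scores that kept every library or left out the 3 shallow ones. All 80 called genes kept their sign under every alternative in which they were tested, which was likely in advance for genes chosen by p in these libraries. With the glial covariates their folds shrank, that of APOD from 2.71 to 0.75 and that of CD74 from 2.10 to 0.22. Over unfiltered markers the microglia score went from 1.29 to 0.87 and the endothelial score from 1.06 to 0.57, and with a pseudocount of 0.1 they were 2.02 and 1.76. On the deposited log scale the microglia score difference was 2.31. The number of genes passing did not hold. Against 70 higher and 10 lower, limma called 164 and 19 with a pseudocount of 0.1, 156 and 16 on the deposited log scale, 778 and 87 with array weights, 40 and 7 with robust eBayes, 43 and 6 after thinning to the shallowest library, 48 and 4 without the 3 libraries under 3000000 reads, 64 and 34 with quantile normalization, 64 and 40 with median centring and 95 and 26 when rescaled without the 10 highest genes. It called 0 and 0 with no filter (2719 at an unadjusted p under 0.05), 0 and 0 with voom (1635) and 0 and 0 with the 3 glial scores as covariates (280). Without the filter 17393 genes were tested; for the other changes the cause was not tested. The filter as first written, which kept rows with no read, gave 70 and 9 of 9987 genes, 78 of them shared, and removing the added read gave 71 and 10. Leaving out 1 library gave 0 to 611 genes higher and 0 to 57 lower, each library changing a count by over 1.5 times, with the values per library given in the report.

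Lists called higher and lower were 18 and 11. They were 5 and 1 with the glial covariates, 0 and 0 with these and an estimated correlation, 0 and 0 with an estimated correlation (the smallest unadjusted p was 0.0144), 12 and 6 with a mean RPKM of at least 5, where 33 lists could be run, and 25 and 0 by exact permutation of the list score; leaving out 1 library gave 17 to 20 and 9 to 12. With the glial covariates, camera's direction relative to other genes turned for motor neurons (mean 0.14), pan-neuronal genes (0.16), proteasome (0.12), heat shock (0.22), oxidative phosphorylation (0.18), axonal transport (0.040), synaptic vesicles (0.041) and cholesterol synthesis (0.21). Of the named genes not passing, those that changed sign with these covariates were C3 (-0.063), C7 (-0.017), C9orf72 (0.0087), CXCL12 (-0.0071), GFAP (-0.064), HLA-DRA (-0.038), MBP (-0.038), NEFM (0.030), POLDIP3 (-0.090) and SOD1 (0.25). GFAP, MBP and their like are members of the covariate scores, and for the rest the cause was not tested. CHAT turned to 0.029 with array weights, C9orf72 to 0.032 with the motor neuron score as a covariate and 0.011 with voom, and SOD1 to 0.024 without the 3 shallow libraries; the cause was not tested. Leaving out 1 library moved CHAT between -0.16 and 0.21 (0.21 without control 1) and C9orf72 between -0.21 and 0.044. The score of neurofilaments and large neurons passed with median centring (-0.48, adjusted p = 0.0223) and rescaling (-0.37, adjusted p = 0.0405), with an adjusted p of 0.0223 to 0.708 over the alternatives that kept every library or left out the shallow ones. Leaving out 1 library gave 1.09 to 1.45 for the astrocyte score, lost without control 2 (adjusted p = 0.0528), and 0.97 to 1.27 for the oligodendrocyte score, lost without control 2, 3 or 8 or sALS 1, 2, 5, 10 or 11 (adjusted p up to 0.0691). The second expression table holds no values per library, so that alternative was not run. Depth limits the low genes most: in sALS 12, the shallowest library, 1 read in a gene of median length was 0.124 RPKM, against 0.0216 RPKM in sALS 6. No paired analysis was possible because the numbers of control and sALS libraries only name separate donors.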

Other observations

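The settings with voom, thinning, covariates joined with an estimated correlation, rescaling, the deposited log scale, rows with no read and without the 3 shallow libraries were chosen only after the results had been seen, and no other test in this section was. Camera called 4 further lists higher at its preset correlation: immediate early genes, apoptosis and p53 targets, lysosome and unfolded protein response. Of 10 immediate early genes, which respond to cell stimulation, none rose over all genes by limma and 7 adjusted over the list alone (median log2 fold change 0.65, adjusted p = 0.221 with an estimated correlation), EGR1 (1.40, adjusted p = 0.0532) and FOS (1.39, adjusted p = 0.0534) standing highest by p. Of 17 apoptosis and p53 target genes none rose over all genes by limma and 3 adjusted over the list alone (median 0.46, adjusted p = 0.358 with an estimated correlation); the cell cycle inhibitor CDKN1A was at 5.80 ± 2.42 RPKM in controls (SD, n = 8) and 26.9 ± 40.9 RPKM in sALS (SD, n = 12, 1.48, adjusted p = 0.0534), and camera's call was lost with a mean RPKM of at least 5 (mean 0.38, adjusted p = 0.260). Of 26 lysosome genes 1 rose, GPNMB, and 4 adjusted over the list alone (median 0.29, adjusted p = 0.409 with an estimated correlation), while the ceramidase ASAH1 had a log2 fold change of 0.80 (adjusted p = 0.0529); camera's call was lost without control 7 (mean 0.36, adjusted p = 0.0536). Of 22 unfolded protein response genes 0 rose by limma over all genes and 4 adjusted over the list alone (median 0.29, adjusted p = 0.380 with an estimated correlation), the chaperone HSP90B1 having a log2 fold change of 0.53 (adjusted p = 0.0577). That call was lost without control 3 (mean 0.33, adjusted p = 0.0512), control 7 (0.35, 0.0797), control 8 (0.32, 0.0747), sALS 3 (0.35, 0.0646), sALS 4 (0.37, 0.0623), sALS 5 (0.29, 0.0664), sALS 7 (0.31, 0.0503), sALS 9 (0.34, 0.0712) or sALS 12 (0.32, 0.0629). It was also lost with quantile normalization (0.17, 0.0517), median centring (0.11, 0.0932), voom (0.36, 0.0571), rescaling without the 10 highest genes (0.24, 0.0808), the motor neuron score as a covariate (0.31, 0.0542) and without the 3 libraries under 3000000 reads (0.29, 0.183). With the 3 glial scores as covariates the means went from 0.81 to 0.19, 0.47 to 0.03, 0.35 to 0.08 and 0.34 to 0.03 for the 4 lists in this order. With median centring the means were 0.58, 0.24, 0.12 and 0.11 in the same order.

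Genes of neuronal structure and transmission were called lower relative to other genes. Of 24 genes of the microtubule and actin cytoskeleton 0 passed over all genes by limma, with 2 higher and 4 lower adjusted over the list alone (median -0.11, adjusted p = 0.202 with an estimated correlation), and MAP2, a dendritic microtubule protein, was at -0.55 (adjusted p = 0.102). Synaptic vesicle genes had 0 of 30 passing by limma over all genes or adjusted over the list alone (median -0.08, adjusted p = 0.238 with an estimated correlation). Of 18 receptors for GABA, glycine and acetylcholine 0 passed by limma over all genes and 1 fell adjusted over the list alone (median -0.20, adjusted p = 0.202 with an estimated correlation); the muscarinic receptor CHRM2 did not pass (-0.62, adjusted p = 0.0607, 12 of 12 below the control median). Of 12 glutamate receptors 0 passed by limma over all genes, with 1 higher and 1 lower adjusted over the list alone (median -0.05, adjusted p = 0.202 with an estimated correlation), GRIN2A being at -0.53 (adjusted p = 0.0986); the call was lost without control 1 (mean -0.01, adjusted p = 0.0574). Axonal transport motors (median -0.05, adjusted p = 0.202 with an estimated correlation) and the proteasome (median -0.03, adjusted p = 0.406 with an estimated correlation) had 0 genes passing by limma of 29 and 26. Camera's call for transport motors was lost with a mean RPKM of at least 5 (mean -0.01, adjusted p = 0.0892), and that for cytoskeleton with quantile normalization (-0.16, adjusted p = 0.115). Given the 3 glial scores as covariates, the means were -0.06 for cytoskeleton, 0.04 for synaptic vesicles, -0.02 for GABA, glycine and acetylcholine receptors, -0.13 for glutamate receptors, 0.04 for transport motors and 0.12 for the proteasome. The size of these changes depended on the scaling: as deposited the means were -0.08, -0.05, -0.05, -0.08, -0.03 and -0.05 in this order, against -0.31, -0.28, -0.27, -0.31, -0.25 and -0.27 with median centring, where all 6 stayed called.

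Camera did not call 14 lists, ALS-linked genes and interneuron markers among them. Growth factor and neurotrophin signalling had 1 of 26 genes higher, IGF2, and 9 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.0539, and 0.563 with an estimated correlation). It was called without control 1 (mean 0.57, adjusted p = 0.0228), control 4 (0.53, 0.0477), control 7 (0.60, 0.0226), sALS 2 (0.499, 0.0443), sALS 6 (0.58, 0.0314), sALS 8 (0.58, 0.0230), sALS 9 (0.55, 0.0494) or sALS 11 (0.53, 0.0351). It was also called with a pseudocount of 0.1 (0.81, 0.0460), no filter (0.41, 0.00963), quantile normalization (0.34, 0.00918), median centring (0.30, 0.00598), array weights (0.52, 0.0387), thinning (0.52, 0.0408), rescaling (0.43, 0.0254), the deposited log scale (0.92, 0.0495) and the rows with no read kept (0.53, 0.0325). Matrix metalloproteinases and their inhibitors had 0 of 11 genes passing by limma over all genes, with 5 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.0539, and 0.317 with an estimated correlation). They were called without control 2 (0.64, 0.0466), sALS 2 (0.62, 0.0442), sALS 5 (0.53, 0.0415), sALS 8 (0.68, 0.0465), sALS 10 (0.66, 0.0450) or sALS 11 (0.63, 0.0330). They were also called with a pseudocount of 0.1 (0.91, 0.0366), no filter (0.46, 0.0114), a mean RPKM of at least 5 (0.98, 0.00548), quantile normalization (0.46, 0.0276), median centring (0.41, 0.0218), array weights (0.61, 0.0432), thinning (0.65, 0.0258), rescaling (0.54, 0.0383), the deposited log scale (1.01, 0.0408) and the rows with no read kept (0.64, 0.0333). Antioxidant and metal binding genes had 2 of 20 higher, and 2 adjusted over the list alone, the quinone reductase NQO1 (0.92, limma adjusted p = 0.0366, 12 of 12) and FTL (1.39, adjusted p = 0.0454, 12 of 12). Of cell cycle genes 1 of 9 rose (CCND1) and 3 adjusted over the list alone, of heat shock and chaperone genes 1 of 25 (CRYAB) and 2 adjusted over the list alone, and of cell adhesion receptors 2 of 31, PECAM1 among them, and 7 adjusted over the list alone. For hypoxia and glycolysis 0 of 25 genes passed by limma over all genes and 5 adjusted over the list alone, with ADM, a vasodilator peptide, at 1.5 (adjusted p = 0.0577). These 7 lists were all higher by the exact permutation test of list scores, with adjusted p from 0.0104 (metalloproteinases) to 0.0247 (growth factors). With median centring the means went from 0.23 to 0.0091 for heat shock, 0.25 to 0.028 for antioxidant genes and 0.30 to 0.076 for hypoxia. They went from 0.38 to 0.15 for adhesion receptors and 0.48 to 0.25 for cell cycle. With the 3 glial scores as covariates the means were -0.07 for growth factors, 0.04 for metalloproteinases, 0.05 for antioxidant genes, 0.05 for cell cycle, 0.22 for heat shock (called higher by camera at the preset correlation, adjusted p = 3.2e-04, and 0.796 with an estimated one; without covariates camera did not call it, with adjusted p = 0.866 at an estimated correlation), 0.05 for adhesion receptors and 0.03 for hypoxia.

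Oxidative phosphorylation genes had a mean of 0.07 and 0 of 60 passing by limma over all genes or adjusted over the list alone; the mean was -0.16 with median centring. Relative to other genes they were called lower without control 1 (mean 0.02, adjusted p = 0.0178), control 5 (0.04, 0.0363), sALS 2 (0.02, 0.0260), sALS 6 (0.04, 0.0285) or sALS 8 (0.05, 0.0465), and higher with the 3 glial scores as covariates (0.18, adjusted p = 3.2e-04, and 0.814 with an estimated correlation besides). Without covariates the adjusted p with an estimated correlation was 0.787. Genes of axon injury and regeneration had 1 of 16 higher, GPNMB, with 3 higher and 2 lower adjusted over the list alone. HOX genes (0 of 14 passing by limma, mean 0.28), autophagy (0 of 19, 0.13) and cholesterol synthesis (0 of 17, 0.07) were not called by camera or by the exact permutation test as deposited. The means of HOX genes, autophagy and cholesterol synthesis were 0.059, -0.10 and -0.16 with median centring. With the 3 glial scores as covariates cholesterol synthesis was called higher at the preset correlation (0.21, adjusted p = 0.00738), but not with an estimated one (0.814, and 0.841 without covariates).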
